A study of Homo sapiens with 12 samples.

How the data were processed

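The series followed human HEK293T Flp-In cells after 2 h with DMSO or with girolline at 1 or 10 µM. The labels name 12 libraries of 3 kinds. Poly(A) RNA-seq measured mRNA level, monosome footprints measured fragments protected by lone ribosomes, and disome footprints measured longer fragments protected by a pair of adjoining ribosomes. Each kind had 2 DMSO libraries, 1 library at 1 µM and 1 library at 10 µM. Per the labels' protocols, profiling libraries were made with RNase I digestion, ribosome pelleting, size selection, linker ligation and rRNA depletion, and RNA-seq libraries with Illumina's stranded mRNA kit.

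The authors deposited 1 table per library with raw read counts per transcript, without normalization. Per the submitters' processing notes, the genome build was hg38 and the tools named were STAR 2.7.0a and CASAVA 1.8, with no role stated for either. The counting tool, the annotation release and the handling of reads that match several places were not given in the sources used here. Each deposited table holds a transcript ID, a length and a count. RNA-seq and disome tables list 182398 transcripts with UCSC IDs, of which 93916 have a coding length. Monosome tables list 227264 transcripts with Ensembl IDs, of which 100283 have one. Transcripts with no coding length had a total count of 0 and were left out.

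The length values of the RNA-seq tables lie 20 below those of the disome tables for every transcript. The lowest values were -19 in RNA-seq, -9 in monosome and 1 in disome tables, and the highest 35972, 35982 and 35992. The disome value was therefore taken as the coding length, with 20 added in RNA-seq and 10 in monosome tables. Codons were inferred as the unit from the values, since 33.1% of them are multiples of 3. The shorter lengths in RNA-seq and monosome tables point to counting over part of the coding region, which leaves fewer reads for the shortest transcripts in every library of a kind alike. Between kinds the part left out differs, so disome counts may include coding ends that RNA-seq counts omit. Comparisons of kinds by length, the ratio included, may therefore set unlike regions side by side.

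The files do not pair transcript IDs with gene names, and no table used here does. Gene lists, codon groups and shares of reads in untranslated regions, which had been planned, were therefore not analysed here. Monosome tables use other IDs than the rest, so ratios of monosome to RNA-seq or disome values per transcript and a fit of all 12 libraries were not made. A ratio of disome to RNA-seq values was added once the tables had been seen. Transcripts were grouped instead by coding length, in 6 classes that were also set after the tables had been seen.

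Many neighbouring rows hold identical counts, so reads appear to have been counted in each isoform that holds them, and calls were not treated as independent between isoforms of a gene. Transcripts of a kind with identical counts in all libraries were merged, which left 59394 rows in RNA-seq, 58798 in monosome and 39156 in disome tables. In these tables, 96.5%, 96.2% and 95.5% of identical rows with over 50 counts had a copy within 10 rows. For the tests of length classes and as an alternative for all counts, 1 transcript was kept from each block of 10 consecutive coding rows, the one with the highest mean CPM.

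Total counts per library ran from 28424272 to 42194871 in RNA-seq, from 21570489 to 38074691 in monosome and from 3091715 to 5769026 in disome libraries. If reads were counted once per isoform, these totals exceed the number of reads. The lower disome depth widens counting error for transcripts with few footprints. In the DMSO pairs, the chi-square per degree of freedom over transcripts with at least 20 counts was 6.47 in RNA-seq, 1.69 in monosome and 2.11 in disome libraries, so each pair differed by more than sampling noise. The labels do not say that the DMSO libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

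Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter and the quasi-likelihood test with Benjamini-Hochberg adjustment at an FDR of 0.05. With this scaling, rises and falls are relative to the other transcripts of a library, and a change shared by all transcripts would not show. Each kind was fitted alone with 3 groups over 4 libraries and 1 residual degree of freedom, so the lone library of each dose was assumed to vary like the DMSO pair. The ratio of disome to RNA-seq values was tested as the interaction of kind and dose in a fit of 8 libraries and 6 groups with 2 residual degrees of freedom. Length classes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 6 classes, and again with an estimated correlation. The estimated setting takes its degrees of freedom from the fit, so with 1 or 2 it can hardly reach a small p. Differences between single libraries and rank correlations used log2 CPM with a prior count of 2. Correlations are across transcripts, which are not independent replicates.

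Transcripts to name were those past the FDR at 10 µM with the same sign at 1 µM and a mean of at least 10 CPM, ordered by log2 fold change. With no gene names, 2 that rose and 2 that fell in disome libraries are named and the others summarised. The tests of each kind and the naming rule were set before the data were examined, as were the alternatives of those tests other than unmerged rows, thinned rows and the joint fit. The ratio, the length trends and all their alternatives were set afterwards. The alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter or a mean of at least 1 or 10 CPM, both doses as 1 group, each DMSO library left out, merged or unmerged rows, thinned rows, and a joint fit of RNA-seq and disome libraries.

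The tests were checked on simulated counts drawn from the DMSO means, with 200 transcripts changed 2-fold at 10 µM. The quasi-likelihood test recovered 37% of them among 56229 in RNA-seq, 68% among 55409 in monosome and 21% among 34606 in disome libraries, with 1, 5 and 3 false calls. The ratio of disome to RNA-seq values recovered 4% among 55625, with 0 false calls. Unchanged groups were also simulated 5 times against shared DMSO libraries. These drew each transcript independently, with the fitted spread in every library. Their few calls therefore cannot tell whether a dose library varies like the DMSO pair. Figures were drawn with matplotlib 3.10.9.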

Results

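The libraries came from HEK293T Flp-In cells, a human embryonic kidney line with an engineered site for inserting transgenes. The cells were exposed for 2 h to girolline, a natural product from a marine sponge, at 1 or 10 µM, or to DMSO, its solvent. The series title places girolline's action at eIF5A, a translation factor that helps ribosomes past slow stretches of coding sequence and at stop codons, and ties it to sequence context. RNA-seq, monosome and disome libraries each held 2 DMSO libraries and 1 library per dose. Total counts were 32586618 and 42194871 in the RNA-seq DMSO libraries, 39132674 at 1 µM and 28424272 at 10 µM. Monosome libraries held 29278822 and 34873134 with DMSO, 21570489 at 1 µM and 38074691 at 10 µM. Disome libraries held 3091715 and 5151900 with DMSO, 4704075 at 1 µM and 5769026 at 10 µM.

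The first comparison asked whether girolline altered mRNA levels within 2 h. At 10 µM few mRNAs passed the test, and those that did were mostly lower among short coding regions and mostly higher among long ones. Among mRNAs under 100 codons, 172 of 8123 fell and 12 rose. Isoforms share reads, and with 1 transcript kept per block 15 of 177 fell and 0 rose in this class. Kept that way, 22 of 1384 of the longest class rose and 0 fell. At 200 to 299 codons 26 rises and 20 falls became 4 and 18, and at 300 to 499 codons 48 and 3 became 9 and 7. Among mRNAs of 1000 codons or more, 42 of 4286 rose and 1 fell, and among those of 500 to 999 codons 86 of 10217 rose and 0 fell by the quasi-likelihood test. In total 302 of 56229 mRNAs rose and 321 fell at an FDR of 0.05, with median log2 fold changes of 0.99 and -0.99 among those called. At 1 µM, edgeR's quasi-likelihood test called 0 of 56229, where 557 had an unadjusted p under 0.05 and DESeq2 also called 0.

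With 1 transcript kept per block, mRNAs under 100 codons had a median log2 fold change of -0.29 at 10 µM and those of 1000 codons or more 0.14, where all tested mRNAs of these classes gave -0.17 and 0.17. Camera with the preset correlation gave adjusted p = 1.26e-13 for the shortest class and 2.93e-11 for the longest. These calls were lost with an estimated correlation, at adjusted p = 0.107 and adjusted p = 0.121 in turn. The 1 µM library had thinned medians of -0.12 and 0.04 in these classes, against -0.04 and 0.05 over all tested mRNAs, with adjusted p = 5.11e-08 and 4.53e-05 at the preset correlation and adjusted p = 0.188 and 0.194 with an estimated correlation. The median of DMSO 2 against DMSO 1 was 0.001 on the log2 scale in the shortest class and 0.04 in the longest, while that of the 10 µM library was -0.156 and -0.14 against the DMSO libraries in the shortest class and 0.185 and 0.165 in the longest. Spearman's rho between coding length and log2 change was 0.236 across transcripts at 10 µM, 0.0928 at 1 µM and 0.0014 for DMSO 2 against DMSO 1. The 8 highest mRNAs at 10 µM by the naming rule spanned 127 to 368 codons at log2 fold changes of 1.54 to 2.11, and the 8 lowest spanned 26 to 67 codons at -1.41 to -1.80. DESeq2 called 225 mRNAs at 10 µM in place of 623, and 2 were called when both doses formed 1 group. In a fit with the disome libraries, 389 rose and 524 fell without RNA-seq DMSO 1, and 255 and 504 without DMSO 2. The fit with the disome libraries and none left out gave 302 rises and 429 falls. Keeping 1 transcript per block gave 162 calls among 8743.

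The monosome comparison asked whether ribosome occupancy of coding regions shifted. At 10 µM, the calls among the longest coding regions were mostly falls, and those among regions under 500 codons were more often rises. Among coding regions of 1000 codons or more, 1484 of 4347 fell and 255 rose, and with 1 transcript per block 452 of 1327 fell and 116 rose. Among those of 200 to 299 codons 1682 of 8024 rose and 1173 fell, and among those under 100 codons 1243 of 8451 rose and 782 fell. Over all lengths 9181 of 55409 rose and 8702 fell, with median log2 fold changes of 0.65 and -0.51. At 1 µM 580 rose and 404 fell, with medians of 0.41 and -0.35.

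At 1 µM, 120 of the 4347 longest coding regions fell and 1 rose, while 191 of the 8451 shortest rose and 25 fell. Thinned to 1 transcript per block, the longest class had a median log2 fold change of -0.09 at 1 µM and -0.14 at 10 µM, against -0.11 and -0.20 over all tested. Camera at the preset correlation gave adjusted p = 3.76e-10 and 7.89e-06 for that class, and adjusted p = 0.264 and 0.514 with an estimated correlation. The shortest class had a thinned median of 0.11 at 1 µM, against 0.07 over all tested, with adjusted p = 1.02e-06 at the preset correlation and adjusted p = 0.264 with an estimated correlation. At 10 µM its thinned median was 0.05, against 0.07 over all tested, and it did not pass at either setting (adjusted p = 0.305 and 0.644). The classes of 100 to 199, 200 to 299 and 300 to 499 codons did not pass at 10 µM either, with adjusted p = 0.207, 0.106 and 0.207 at the preset correlation and 0.514 for each with an estimated correlation. Against single DMSO libraries, the longest class had median log2 ratios of -0.178 and -0.202 at 10 µM, beside 0.029 for DMSO 2 against DMSO 1. Spearman's rho with coding length was -0.134 across transcripts at 10 µM and 0.016 for the DMSO pair, but at 10 CPM or more the DMSO pair itself gave 0.134, beside -0.129 and -0.167 for 10 µM against each DMSO library. Few changes were large among the 16522 transcripts with at least 10 CPM, called or not. Of these, 1.30% and 1.54% differed over 2-fold between 10 µM and each DMSO library, and none did between the DMSO libraries. The coefficient of variation from the common dispersion was 3.85%, against 11.8% in RNA-seq. DESeq2 called 3514 at 10 µM, 36.8% of them higher against 51.3% with edgeR, and 258 at 1 µM, 69.8% of them higher against 58.9%. With both doses as 1 group edgeR called 0, where 9093 had an unadjusted p under 0.05 and DESeq2 was not run, and 1 transcript per block gave 3893 calls among 9151 at 10 µM and 253 at 1 µM.

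**Figure D1:**
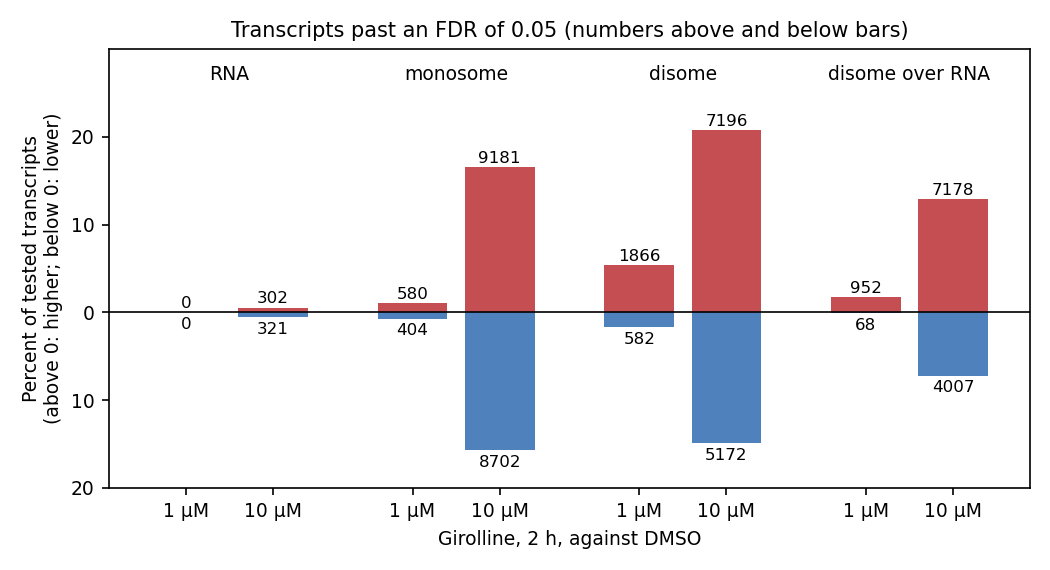
Bars show the percent of tested transcripts that passed an FDR of 0.05 in edgeR's quasi-likelihood test at 1 and 10 µM girolline against DMSO, with higher transcripts above 0 and lower ones below. Printed numbers are transcripts: disome libraries had 7196 higher and 5172 lower at 10 µM, and RNA-seq 302 and 321.

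The disome comparison asked on which transcripts footprints of adjoining ribosomes changed. The counts hold no positions and were not set against monosome footprints, so queuing cannot be told from a change in ribosome load. Relative to the other transcripts of a library, disome footprints rose more often than they fell on short coding regions, at both doses. On those of 1000 codons or more they fell more often than they rose, at both doses. At 500 to 999 codons falls led at 10 µM, but at 1 µM 88 rises and 162 falls became 40 and 31 with 1 transcript per block. At 10 µM, 986 of 2939 coding regions under 100 codons rose and 288 fell, and 2635 of 8637 of 100 to 199 codons rose and 788 fell. Among coding regions of 1000 codons or more, 1248 of 3276 fell and 37 rose, and among those of 500 to 999 codons 1486 of 7697 fell and 663 rose. With 1 transcript per block, 91 of 197 in the shortest class rose and 18 fell, and 425 of 1242 in the longest fell and 20 rose. In all, 7196 of 34606 rose and 5172 fell, with median log2 fold changes of 1.39 and -1.06.

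At 1 µM, 1866 rose and 582 fell, with medians of 1.10 and -0.91. Among the longest coding regions 191 of 3276 fell and 2 rose at this dose, and among the shortest 315 of 2939 rose and 40 fell. With 1 transcript per block, the median log2 fold change at 10 µM was 0.65 under 100 codons, 0.54 at 100 to 199, 0.51 at 200 to 299, 0.19 at 300 to 499, -0.14 at 500 to 999 and -0.51 at 1000 or more. Over all tested transcripts the medians of these classes were 0.44, 0.34, 0.26, 0.05, -0.26 and -0.60 in the same order. Camera at the preset correlation gave adjusted p = 8.31e-07 for the shortest class and 3.6e-15 for the longest, and adjusted p = 0.458 for each with an estimated correlation. At 1 µM the thinned medians of these classes were 0.31 and -0.29, against 0.19 and -0.32 over all tested, with adjusted p = 5.7e-06 and 2.28e-16 at the preset correlation and adjusted p = 0.412 and 0.398 with an estimated correlation. No length class kept its call with an estimated correlation, in any kind of library. In RNA-seq at 10 µM the shortest class lost its call although its estimated correlation, -0.00308, lay below the preset 0.01. With 1 residual degree of freedom for a kind and 2 for the ratio, this setting can hardly reach a small p. The loss alone therefore does not show that correlation between transcripts makes the trends. In disome libraries at 10 µM, though, the estimated correlations were 0.173 in the shortest class and 0.134 in the longest, far above the preset. The adjusted p at the preset correlation may therefore be too small there, and correlation may account for part of the loss. For DMSO 2 against DMSO 1 the median was -0.042 in the shortest class and 0.092 in the longest. The sign of this pair depends only on the order of its libraries. In size these lay below 10 µM against each DMSO library, at 0.417 and 0.464 in the shortest class and -0.516 and -0.597 in the longest. Spearman's rho with coding length was -0.321 across transcripts at 10 µM, -0.267 at 1 µM and 0.093 for DMSO 2 against DMSO 1.

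Disome changes were larger than those in the other libraries. Of 14539 transcripts with at least 10 CPM, 25.3% and 24.9% differed over 2-fold between 10 µM and each DMSO library, against 0.461% between the DMSO libraries. At 1 µM the shares were 5.77% and 5.60%. Over 2-fold above both DMSO libraries lay 1819 transcripts at 10 µM and 453 at 1 µM, and below both 1037 and 25. By the naming rule 3496 transcripts rose and 3304 fell, with median coding lengths of 223 and 676.5 codons. The 8 highest of these spanned 36 to 161 codons and the 8 lowest 17 to 214, so the largest falls were not on long coding regions.

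The files do not pair the transcript IDs with gene names, so the first 2 in each direction are given by ID. Transcript uc063cag.1, of 36 codons, had 1 and 5 disome counts with DMSO, 39 at 1 µM and 154 at 10 µM. Its log2 fold change at 10 µM was 5.25 (SE 0.40), with adjusted p = 4.28e-37 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It rests on few DMSO counts, and was 4.82 without DMSO 1 and 6.40 without DMSO 2. Transcript uc064mql.1, of 70 codons, had 4 and 8 counts with DMSO, 31 at 1 µM and 168 at 10 µM, a log2 fold change of 4.40 (SE 0.35) at 10 µM, with adjusted p = 2.78e-34 in the same edgeR test. Transcript uc058ivk.1, of 194 codons, had 52 and 68 counts with DMSO, 25 at 1 µM and 7 at 10 µM. Its log2 fold change was -3.47 (SE 0.44), with adjusted p = 6.64e-14 in the same edgeR test. Transcript uc058oso.1, of 17 codons, had 45 and 100 counts with DMSO, 26 at 1 µM and 6 at 10 µM, a log2 fold change of -3.93 (SE 0.44) with adjusted p = 2.87e-17 in the same edgeR test. Their log2 fold changes at 1 µM, whose sign the naming rule fixed, were 3.53, 2.23, -1.40 and -1.58.

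DESeq2 called 2591 disome transcripts at 10 µM and 279 at 1 µM, of which 96.4% were higher at 1 µM against 76.2% with edgeR, and both doses as 1 group gave 972 rises and 53 falls. A joint fit with all RNA-seq and disome libraries gave 7593 rises and 4638 falls at 10 µM, the base for the fits below with a library left out. In a fit with the RNA-seq libraries, leaving out disome DMSO 1 gave 917 rises and 337 falls at 1 µM and leaving out DMSO 2 gave 769 and 91, while all libraries in that fit gave 1872 and 270. Without DMSO 2 there were 5152 rises and 3323 falls at 10 µM, and 1 transcript per block gave 2932 at 10 µM and 607 at 1 µM among 7843.

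**Figure D2:**
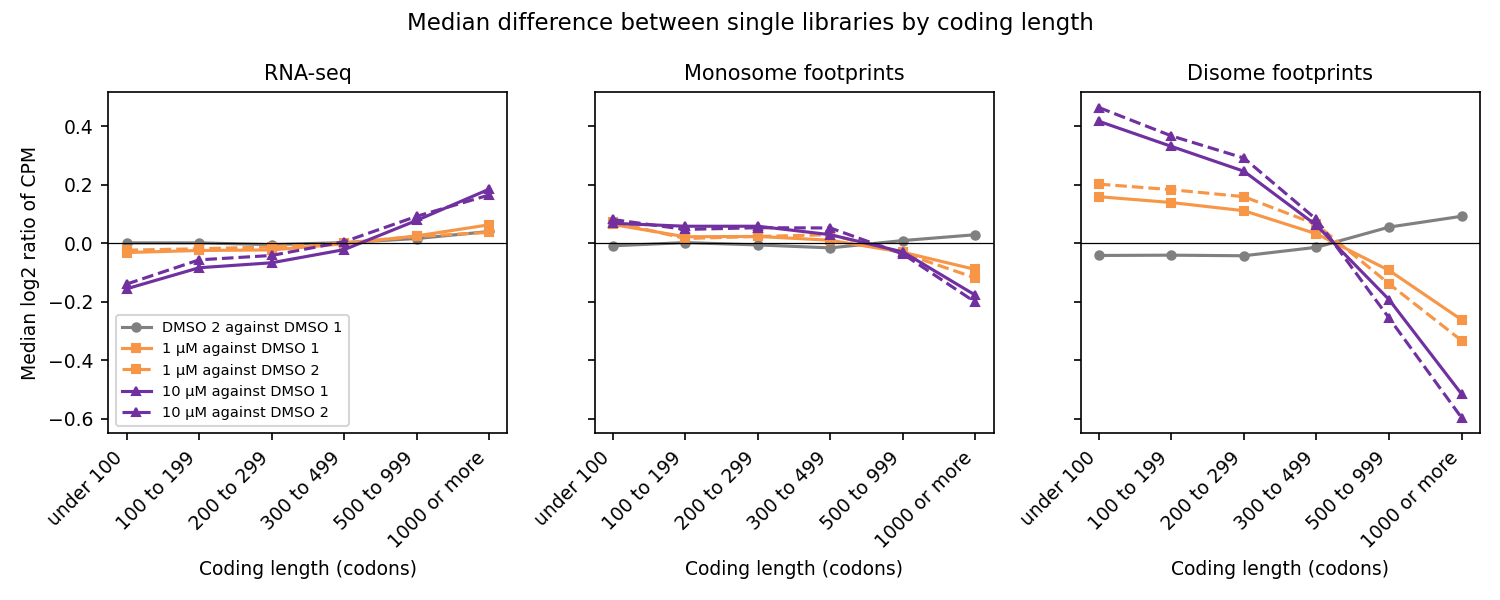
Points give the median log2 ratio of CPM between pairs of single libraries, by coding length in codons, for RNA-seq, monosome and disome libraries. At 1000 codons or more, the 10 µM disome library lies at -0.516 and -0.597 against the DMSO libraries, the monosome library at -0.178 and -0.202 and the RNA-seq library at 0.185 and 0.165.

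The disome and RNA-seq libraries share transcript IDs, so disome change was also set against mRNA change. This ratio does not separate queuing from ribosome load either. Relative to mRNA, disome footprints at 10 µM rose on 7178 of 55625 transcripts and fell on 4007. Among coding regions of 1000 codons or more 1182 of 4240 fell and 23 rose, and among those under 100 codons 1225 of 7863 rose and 152 fell. With 1 transcript per block, 457 of 1336 of the former fell and 13 rose, and 95 of 203 of the latter rose and 9 fell. Median RNA-seq log2 fold changes were -0.15 where disome footprints rose and 0.1 where they fell. Few mRNAs were called among the 33359 transcripts tested in both kinds, 252 higher and 272 lower, which limits any overlap. Of 6887 of these with raised disome footprints, 57 rose and 171 fell in RNA-seq, and of 4921 with lowered footprints 56 rose and 24 fell.

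With 1 transcript per block, the median log2 change of the ratio at 10 µM was 1.09 under 100 codons and -0.65 at 1000 or more, against 0.50 and -0.73 over all tested transcripts. Camera at the preset correlation gave adjusted p = 1.29e-10 and 2.34e-18, and adjusted p = 0.116 for each with an estimated correlation. Pearson's correlation of the disome and RNA-seq log2 fold changes was -0.236 at 10 µM and -0.0329 at 1 µM, across 33359 transcripts. Of the 7196 transcripts with raised disome footprints 5890 also rose relative to mRNA, and of the 5172 with lowered footprints 3247 also fell. Both tests use the same disome counts, so this overlap is no separate support. Transcripts uc063cag.1 and uc064mql.1 rose relative to mRNA by 7.74 and 4.20 on the log2 scale, and uc058ivk.1 fell by 3.66, with adjusted p = 1.42e-22, 1.53e-14 and 4.92e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The ratio of uc063cag.1 was 7.23 without disome DMSO 1 and 8.81 without disome DMSO 2. In RNA-seq alone uc063cag.1 fell by 2.41 on the log2 scale at 10 µM, with adjusted p = 0.0289 by the same edgeR test, and uc064mql.1 and uc058ivk.1 had 0.27 and 0.21, with adjusted p = 0.824 and 0.811. The RNA-seq mean of uc063cag.1 lay under 1 CPM, with 20 of its 36 codons left out there. Its RNA-seq fall and its ratio therefore rest on low values. Transcript uc058oso.1 is shorter than the 20 codons left out in RNA-seq and had no counts there, so no ratio is given. At 1 µM, 952 transcripts rose relative to mRNA and 68 fell. DESeq2 called 6161 at 10 µM and 336 at 1 µM, both doses as 1 group gave 1948 rises and 373 falls, and 1 transcript per block gave 2688 and 248. At 1 µM, leaving out disome DMSO 1 gave 521 rises and 122 falls, disome DMSO 2 446 and 18, RNA-seq DMSO 1 1019 and 108, and RNA-seq DMSO 2 820 and 151. DESeq2 size factors in edgeR gave 810 and 108, a mean of at least 10 CPM 768 and 167, and DESeq2 330 and 6.

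**Figure D3:**
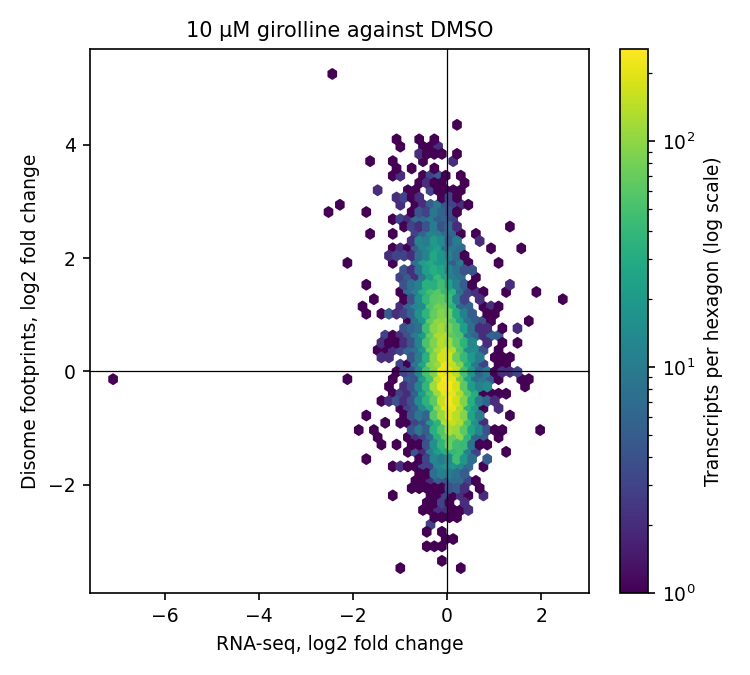
Hexagons show how many of 13816 transcripts with at least 10 CPM in disome libraries have a given log2 fold change in RNA-seq (horizontal) and in disome footprints (vertical) at 10 µM against DMSO, with color on a log scale. The cloud is taller than wide and tilts downward, with a Pearson correlation of -0.32 across transcripts.

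The doses were also set against each other. From 1 to 10 µM, 2665 of 34606 transcripts rose and 1509 fell in disome footprints, 3207 of 55409 rose and 3511 fell in monosome footprints, and 123 of 56229 rose and 117 fell in RNA-seq. Relative to mRNA, disome footprints rose on 1787 transcripts and fell on 948. Of the disome transcripts that rose at 1 µM, 1718 of 1866 also rose at 10 µM, where independent lists would share 388, and of those that fell 487 of 582 also fell, where independent lists would share 87.0. In monosome libraries 511 of 580 rose at both doses, against 96.1 for independent lists, and 376 of 404 fell, against 63.4. Of the 623 RNA-seq transcripts called at 10 µM, 77.5% had the same sign at 1 µM, below the 83.5% of as many transcripts with the lowest p in simulated unchanged groups that share the DMSO pair.

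Both doses share the DMSO pair, and unchanged groups simulated against it also correlate. In disome libraries the log2 changes at 1 and 10 µM had a Pearson correlation of 0.681 and a covariance of 0.385, against 0.384 and 0.0634 when simulated, a difference in covariance of 0.321. In monosome libraries the correlation was 0.455 and the covariance 0.0796, against 0.308 and 0.0238. In RNA-seq the correlation was 0.257 and the covariance 0.0288, below the simulated 0.324 and 0.0355. At most 1 transcript was called per simulated dose and 0 at both, and over all transcripts 75.6% of disome changes had the same sign at both doses against 62.2% when simulated, and 60.4% of RNA-seq changes against 60.7%. The DMSO pairs are too few to split, so part of the excess may come from the shared controls. DESeq2 called 430 disome, 711 monosome, 86 RNA-seq and 947 ratio differences between the doses, with 27% of the monosome calls higher against 47.7% with edgeR. Keeping 1 transcript per block gave 981, 1625, 51 and 821.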

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

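The test of length trends against single DMSO libraries was chosen after the trends had been seen, as were the length classes and the comparison of disome footprints with mRNA.

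At 10 µM girolline, disome and mRNA changes differed by coding length in the test of the interaction of kind and dose at the preset correlation. The median log2 change of disome footprints relative to mRNA was 1.09 for coding regions under 100 codons and -0.65 for those of 1000 codons or more with 1 transcript per block, and 0.50 and -0.73 over all tested transcripts. The class difference was lost with an estimated correlation (adjusted p = 0.116 for each class by camera), a setting that can hardly pass with 2 residual degrees of freedom. Among single transcripts the same test gave 7.74 for uc063cag.1 (7.23 without disome DMSO 1 and 8.81 without disome DMSO 2) and 4.20 for uc064mql.1, where disome footprints rose relative to mRNA. The value of uc063cag.1 rests on an RNA-seq mean under 1 CPM. The test gave -3.66 for uc058ivk.1, where disome footprints fell relative to mRNA.

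The opposite length trends, a rho of 0.236 in RNA-seq and -0.321 in disome footprints at 10 µM, were set against 3 technical explanations. Reads counted in several isoforms are argued against, since 1 transcript per block gave 0.385 and -0.417. Blocks are not genes, however, and 6.11% of thinned RNA-seq and 7.49% of thinned disome rows still repeated the counts of another. Sharing between isoforms is therefore not fully excluded. Few reads per transcript do not account for the trends, since transcripts of at least 10 CPM gave 0.435 and -0.397. A difference of the size seen between DMSO libraries is also argued against, with smaller values of 0.214 and -0.285 against single DMSO libraries beside 0.0014 and 0.093 for the DMSO pair, and at 10 CPM or more 0.399 and -0.354 beside 0.0259 and 0.196. A preparation difference that acts on length remains open for each dose library, and a length bias from poly(A) selection remains open for the RNA-seq trend only. Disome counts may also cover coding ends left out in RNA-seq. Each dose has 1 library, and none of these was tested. An effect of girolline that depends on coding length stays open as well, and was not tested apart from these.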

How the results depend on the processing

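Thinning, unmerged rows, the joint fit, every alternative for the ratio of disome to RNA-seq values and every alternative for the length trends were chosen after the data had been seen. No length trend and none of the 73 alternative values of the 4 named transcripts, the ratios of 3 of them included, reversed its direction, and those values kept their side of the threshold. The named transcripts were picked for extreme changes, and every alternative used the same 10 µM libraries, so their stability was nearly fixed by that choice. The ratio of uc063cag.1 was not tested at a mean of at least 1 or 10 CPM, nor that of uc064mql.1 at 10 CPM, since they did not pass these filters. Of 140 alternative values for total calls and length trends, 80 stayed within 1.5 times the total or within the spread of a trend. DESeq2 size factors in edgeR, no filter, a mean of at least 1 CPM, unmerged rows and the joint fit left every total within 1.5 times, but not every direction. Falls in the ratio at 1 µM went from 68 to 108 with size factors, 133 unmerged and 134 at 1 CPM, and disome falls at 1 µM from 582 to 270 in the joint fit. The majority of calls turned where both directions were near equal: in monosome at 10 µM from 51.3% higher to 36.8% with DESeq2 and 49.4% with its size factors, in RNA-seq at 10 µM from 48.5% to 50.2% with size factors and to both of 2 calls with the doses as 1 group, and between the doses from 51.2% to 46.2% in RNA-seq in the joint fit and from 47.7% to 51.7% in monosome at 10 CPM. The other scaling moved the median log2 change by at most 0.012 in size.

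The DESeq2 test called fewer transcripts: 225 in RNA-seq at 10 µM, 258 and 3514 in monosome, 279 and 2591 in disome and 336 and 6161 in the ratio of disome to RNA-seq values at 1 and 10 µM. Between the doses it called 86, 711, 430 and 947 in the same order. The cause was not tested. At a mean of at least 10 CPM fewer transcripts were tested, with 8605 monosome, 7368 disome and 6146 ratio calls at 10 µM and 4277 monosome calls between the doses. Keeping 1 transcript per block, again of fewer tested, gave 162 in RNA-seq at 10 µM, 253 and 3893 in monosome, 607 and 2932 in disome, 248 and 2688 in the ratio, and 51, 1625, 981 and 821 between the doses. Both doses as 1 group, where their difference counts as spread, gave 2 in RNA-seq, 0 in monosome (edgeR; 9093 at an unadjusted p under 0.05), 1025 in disome and 2321 in the ratio.

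Without 1 DMSO library, counts ran from 0 to 3 in RNA-seq at 1 µM (edgeR; 434 at an unadjusted p under 0.05 for the 0), 759 to 913 at 10 µM, 860 to 1254 in disome at 1 µM, 8475 to 10287 at 10 µM, and 464 to 1127 and 8105 to 11780 in the ratio. These fits joined RNA-seq and disome libraries, so the lone DMSO library was assumed to vary like the others. Monosome libraries have other IDs and no spread left without a DMSO library, so no such count was made.

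Length trends were steeper with 1 transcript per block, at rho of 0.254 and 0.385 in RNA-seq, -0.248 and -0.178 in monosome and -0.39 and -0.417 in disome at 1 and 10 µM. At 10 CPM or more they were 0.355 and 0.435, -0.248 and -0.151, and -0.413 and -0.397, where DMSO 2 against DMSO 1 gave 0.0259, 0.134 and 0.196. In monosome at 10 µM the trend there was about the size of that of the DMSO pair. Against single DMSO libraries they ran from 0.0693 to 0.0854 and 0.214 to 0.22 in RNA-seq, -0.131 to -0.122 and -0.128 to -0.126 in monosome, and -0.289 to -0.205 and -0.339 to -0.285 in disome.

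A fit with the DMSO number as a replicate block over RNA-seq and disome libraries gave 13717 ratio calls at 10 µM and 2274 at 1 µM, in place of 11185 and 1020, with 1972 rises and 302 falls at 1 µM in place of 952 and 68. The labels do not say that equal numbers share a culture. DMSO 2 against DMSO 1 correlated between these kinds at 0.0789 across transcripts and at 0.235 at 10 CPM or more, which with 2 numbers leaves a pairing open. The planned ratios over or under monosome values, the fit of 12 libraries, gene lists, codon groups and shares in untranslated regions were not run. Disome libraries had the lowest totals, and 21% of simulated 2-fold changes were recovered there and 4% in the ratio, with no test of how much of this depth sets.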

Other observations

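The lengths of 127 to 131 codons, the 5 lengths from the shortest of the 8 highest RNA-seq transcripts, were picked after those transcripts had been seen, and the count over 2-fold was chosen after the test of their median.

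Coding regions of 1000 codons or more held 10.5% and 11.5% of disome counts with DMSO, 8.29% at 1 µM and 6.67% at 10 µM. Those of 100 to 199 codons went the other way, from 23.3% and 22.7% to 25.8% and 29.6%. In monosome libraries the longest class held 9.27% and 9.49% with DMSO, 8.59% at 1 µM and 8.27% at 10 µM. In RNA-seq it held 12.4% and 12.6%, then 13.2% and 14.3%. The 10 most abundant disome transcripts took 4.15% and 4.11% of counts with DMSO, 3.84% at 1 µM and 2.97% at 10 µM.

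Transcripts of 127 to 131 codons were called higher in RNA-seq at 10 µM in 40 of 940 cases (4.26%), against 0.474% of other lengths. With 1 transcript per block 10 of 61 were called, a share 20.9 times that of other lengths, but the lengths were picked from the same RNA-seq values, so neither share excludes reads shared by isoforms or chance. The test set beforehand against a difference of the size between DMSO libraries showed no rise: over 201 such transcripts with at least 10 CPM the median log2 ratio was -0.052 and -0.075 against the DMSO libraries, beside 0.031 for the DMSO pair. Members went both ways, with quartiles of -0.26 and 0.23, and 16 of the 201 lay over 2-fold above both DMSO libraries, 1 as far below and 0 as far apart between the DMSO libraries, but the lengths were picked for high values, so that explanation also stays open. In libraries not used to pick the lengths, the share called higher at 10 µM with 1 transcript per block was 16.9% against 21.9% of other lengths in monosome footprints, and in disome footprints 27 of 51, beside 424 of 986 in the whole class of 100 to 199 codons, so much of the disome share goes with the general length trend.

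At 10 µM, 17883 monosome and 623 RNA-seq transcripts were called. A closer DMSO pair does not account for the whole gap, since 0.993% of monosome and 0.393% of RNA-seq transcripts with at least 10 CPM differed over 2-fold from both DMSO libraries, a ratio of 2.53. Requiring both libraries is stricter where the pair lies further apart, as in RNA-seq, and the 2 kinds list different transcripts. Against each single DMSO library the shares were 1.30% and 1.54% in monosome and 0.551% and 0.811% in RNA-seq. The ratio of 2.53 is far below the ratio of the calls, and the coefficients of variation were 3.85% and 11.8%. A closer pair may therefore still account for part of the gap. The biological alternative, larger changes in ribosome occupancy than in mRNA at 2 h, stays a hypothesis with 1 library per dose.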
